A study of Mus musculus with 5 samples.

How the data were processed

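The deposited files hold 1 matrix per library of unique molecular identifier (UMI) counts per gene and cell barcode. They were left as the authors deposited them, with no normalization. Per the file headers, the matrices came from Cell Ranger 7.1.0. Per the submitters' processing notes, the reads were demultiplexed with bcl2fastq and aligned to the mouse genome mm39 with Cell Ranger, without further versions. The annotation release is not stated, so no gene coordinates are given. Per the labels' protocols, blood was drawn into an anticoagulant, mononuclear cells were taken from a density gradient, red cells were lysed, and the cells were frozen and thawed before 10x Genomics droplet capture. Every deposited barcode held at least 500 UMIs, and each matrix lists 33,696 genes.

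Barcodes with at least 200 detected genes and a mitochondrial share of UMIs below 10% were kept. Doublets were scored with scrublet as implemented in scanpy 1.11.5, and the top-scoring share of each library was left out. This share grew with the number of barcodes, as the droplet method predicts, and ran from 6.80% to 14.4%. Clusters came from Leiden (leidenalg 0.10.2) at resolution 1 on 40 principal components of 2000 variable genes with 20 neighbours, without integration. A cluster was named after the class whose markers had the highest mean score, if the score was at least 1.5 and at least 3 markers were detected in at least 10% of its cells. The score also had to reach 0.5 of the best score of that class and exceed that of other classes of the same lineage by 0.5, with no class of another lineage at 1.5. Among its 10 leading genes at least 1 had to be a marker of its class, and markers of another class or lineage must not outnumber them. Clusters with at least 50% predicted doublets or under 20 kept cells stayed unnamed. These naming thresholds were set after the data were seen. The unnamed share of kept cells was 1.78% and 3.54% in the chow libraries, 1.39% and 6.81% in the HFD + L-NAME libraries and 1.36% in the NO2-OA library. Classes are called B-like, T-like and so on, because no sort or surface staining defines them.

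Counts were summed per library and class, for classes with at least 50 cells in every library, and over all kept cells. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust quasi-likelihood fit, group as the only term), with Benjamini-Hochberg adjustment within each class at a false discovery rate of 0.05. The 5 libraries shared 1 estimate of the spread. Numbers of cells per class were tested with edgeR, with the total of kept cells as offset. Lists of genes and of cell type markers were tested with camera from limma 3.58.1 on voom values at a preset correlation of 0.01, for lists with at least 5 measured members. Camera was also run with an estimated correlation, and fry was run on the same values. Medians of lists and members above 0 come from the voom values, on the log2 scale with weights for the expected precision of each value. Values of single genes come from edgeR, which weighs counts. The SE printed after ± is the size of the log2 fold change or log2 ratio over the square root of the quasi-likelihood F statistic. It approximates a standard error and is not a spread measured directly between libraries. The lists, the tests and the alternatives below were fixed before the data were examined, except those given as added.

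Genes to be named were set by a rule. In each of the 4 tested classes with most cells and in both comparisons of the regimen and of NO2-OA, the rule took up to 4 risen and 4 fallen genes with the smallest p. They had to pass the threshold, have a mean of at least 4 log2 CPM (UMI counts scaled to equal library totals) and show no overlap between the libraries compared. Gene models without a symbol, immunoglobulin and T-cell receptor segments and pseudogenes were passed over. From each list described, up to 4 members past the threshold were to be named, or else the members with the highest mean. The first part of the rule named Hbb-bs in platelet-like cells alone. Every gene named that neither part gives was chosen after its values were seen, and members that the second part gives were not named in full. Some genes are not reported here. The lists described were chosen after their values were seen, among 192 calls of a gene or marker list in a class over both comparisons, and steadier ones were preferred.

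The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a mitochondrial share below 5%, at least 500 genes, doublets kept, clusters from expression centred within each library, resolution 2, equal numbers of cells per library, and counts thinned to the smallest library. Further alternatives were a block for the replicate number, a fit of 4 libraries alone and each library left out in turn. Shares were also taken without platelet-like, erythroid-like and unnamed cells. Added after the data were seen were B-like cells without cluster 5 or without cluster 11, platelet-like cells from cluster 9 or cluster 12 alone, shares of lymphocytes and monocytes alone, list tests with a block or without 1 library, list medians from edgeR, and the reversal without 1 library. Barcodes under 200 genes were left out of the gene tests. Unnamed clusters and classes with fewer cells were left out of the tests by class, but their counts are part of the sums over all kept cells.

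In a self-test, simulated 4-fold changes for HFD + L-NAME against chow were recovered for 86% of altered genes in B-like, 82% in CD4 T-like, 76% in classical monocyte-like and 51% in platelet-like cells. For 2-fold changes the recovery was 28%, 14.3%, 16% and 10%. For NO2-OA against HFD + L-NAME the recovery of 4-fold changes was 61.2%, 54%, 62% and 20%, and of 2-fold changes 2%, 6%, 16% and 4.08%. Unchanged genes called by error numbered 24, 17, 13 and 9 in these 4 classes for the first comparison and 9, 18, 24 and 3 for the second. Fits, figures and tables used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.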

Results

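Single-cell RNA sequencing was run on mononuclear cells of mouse blood from a model of heart failure with preserved ejection fraction. Chow-fed C57BL/6N mice gave 2 libraries. Mice on a high-fat diet with L-NAME, an inhibitor of nitric oxide synthases, for 15 weeks gave 2 libraries, called HFD + L-NAME. Mice on the same regimen that also received nitro-oleic acid, an electrophilic nitrated fatty acid, for the last 4 weeks gave 1 library, called NO2-OA. The chow libraries held 17,997 and 11,337 barcodes with 122,022,000 and 86,605,300 UMIs, the HFD + L-NAME libraries 12,810 and 8488 barcodes with 89,645,447 and 71,216,133 UMIs, and the NO2-OA library 16,061 barcodes with 109,521,433 UMIs. After filtering, 14,757, 9698, 10,679, 7166 and 12,602 cells were kept in that order. Median depth per barcode ran from 5741 UMIs in the NO2-OA library to 7043.5 in the second HFD + L-NAME library. The labels do not say outright that each library is a separate animal, so p-values measure the spread between libraries alone. The file names split the libraries into sets that coincide with the replicate number, and NO2-OA exists in the first set alone, so values within replicates are given beside pooled values. Low Xist and high Ddx3y levels in CPM, UMI counts scaled to equal library totals (0.0656 to 0.236 and 178 to 236) were found in all 5 libraries.

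The kept cells fell into 10 named classes. B-like cells, which carry Cd79a and Ms4a1, made up 42.6% and 54.4% of the chow libraries, 55.2% and 41.8% of the HFD + L-NAME libraries and 40.1% of the NO2-OA library. CD4 T-like cells made up 16.01% and 12.9%, 12.5% and 5.05%, and 21.5%. CD8 T-like cells made up 21.9% and 13.8%, 12.3% and 5.29%, and 19.1%. Classical monocyte-like cells, which carry Ly6c2 and Ccr2, made up 1.93% and 3.75%, 3.39% and 1.59%, and 4.87%. Non-classical monocyte-like cells made up 4.86% and 5.11%, 3.29% and 2.80%, and 2.55%. No share lay more than 1.15 percentage points from a bound of its exact 95% binomial interval, and these intervals cover counting error only. Genes were tested in B-like (25,497 cells), CD8 T-like (8676), CD4 T-like (8026), platelet-like (3220), non-classical monocyte-like (2086) and classical monocyte-like cells (1739). Summed UMIs per library ran from 28,095,868 to 36,102,597 in B-like, from 3,067,019 to 15,581,644 in CD4 T-like, from 4,331,683 to 24,999,229 in CD8 T-like, from 1,895,611 to 8,804,409 in classical and from 2,304,341 to 5,707,891 in non-classical monocyte-like and from 194,036 to 4,398,118 in platelet-like cells.

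**Figure D1:**
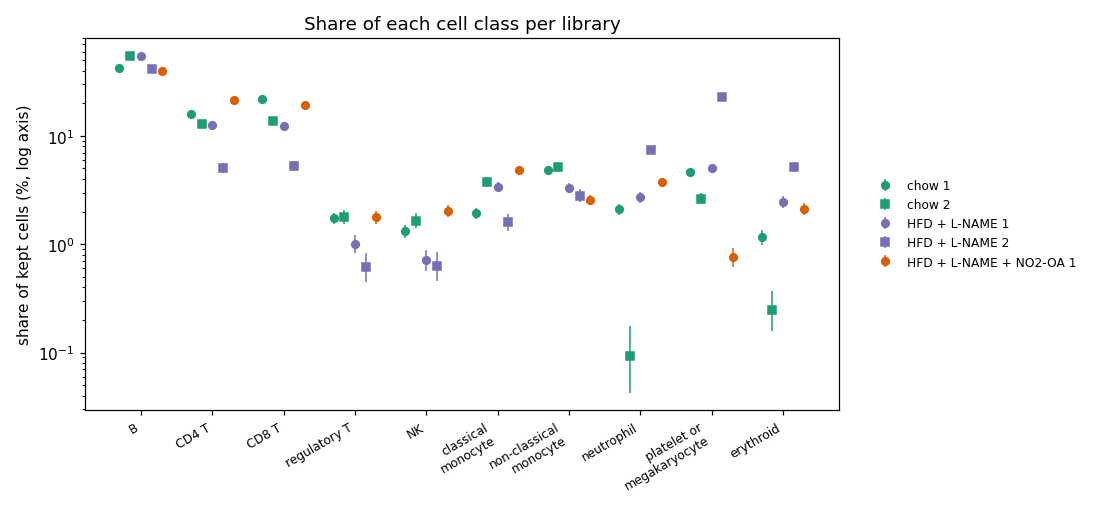
Share of kept cells (%, log axis) in each cell class, with 1 point per library and exact 95% binomial intervals. Platelet-like cells ranged from 0.762% in the NO2-OA library to 22.9% in the second HFD + L-NAME library.

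The comparison of HFD + L-NAME with chow asks how circulating immune cells differed on the regimen. Neutrophil-like, platelet-like and erythroid-like cells made up larger shares, and natural killer (NK)-like, regulatory T-like, CD4 T-like, CD8 T-like and non-classical monocyte-like cells smaller shares, of both HFD + L-NAME libraries than of both chow libraries. Neutrophil-like cells were 2.72% and 7.40% there, against 2.10% and 0.0928% in chow (log2 ratio 2.20 ± 1.56, SE, n = 2 and 2; adjusted p = 0.333). Platelet-like cells were 5.08% and 22.9% against 4.63% and 2.64% (1.94 ± 0.91; adjusted p = 0.256), and erythroid-like cells 2.46% and 5.15% against 1.16% and 0.247% (2.43 ± 0.97; adjusted p = 0.245). NK-like cells, which kill infected or transformed cells, were 0.712% and 0.628% against 1.31% and 1.65% (−1.14 ± 0.42; adjusted p = 0.245), and regulatory T-like cells 1.01% and 0.614% against 1.73% and 1.79% (−1.11 ± 0.47; adjusted p = 0.245). CD8 T-like cells had a log2 ratio of −1.02 ± 0.62 (adjusted p = 0.295; −0.65 without the first chow, −1.76 without the first and −0.54 without the second HFD + L-NAME library). None of the 10 classes passed edgeR, 0 had an unadjusted p under 0.05, and an exact two-sided permutation of 2 against 2 libraries cannot go below 0.33. Of lymphocytes and monocytes alone, CD4 T-like cells were 14.2% in the first HFD + L-NAME library against 13.8% in the second chow library. B-like cells were then higher in both HFD + L-NAME libraries (62.4% and 72.3% against 47.1% and 58.2%). With that total 2 classes had an unadjusted edgeR p under 0.05, and again none passed. The density gradient, red-cell lysis and freezing of the preparation can each set the shares of neutrophils, platelets and red cells. Without the second HFD + L-NAME library the platelet-like log2 ratio was 0.48, and without the first chow library the neutrophil-like log2 ratio was 5.75 and the erythroid-like 3.94.

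In counts summed over all cells, genes of neutrophils and of alarm signalling had log2 fold changes above 0. Such sums move with the shares of cells, but whether these genes followed the shares was not tested. Wfdc21, of the whey acidic protein family, had a log2 fold change of 3.23 ± 0.42 (n = 2 and 2), Mmp8, the neutrophil collagenase, of 2.04 ± 0.34, and Clec4e, a receptor for microbial and damage signals, of 1.54 ± 0.25. S100a8 and S100a9, subunits of the alarmin calprotectin, had 3.53 ± 1.57 and 3.45 ± 1.64. The inflammasome and alarmin genes rose as a list, with 23 of 24 members above 0 and a median of 1.21 (camera adjusted p = 1.00e-19; adjusted p = 0.539 with an estimated correlation). The neutrophil markers rose with 10 of 10 members above 0 and a median of 3.28 (adjusted p = 5.10e-16; adjusted p = 0.498 with an estimated correlation), while medians within replicates were 1.16 and 5.90. NK markers fell, with 0 of 8 members above 0 and a median of −0.89 (adjusted p = 2.91e-10; adjusted p = 0.498 with an estimated correlation), among them the receptors Klra4 (−1.46 ± 0.30) and Klra8 (−1.32 ± 0.28), which passed when adjusted over the list alone, Klrd1 (−0.63 ± 0.27) and Gzma (−1.002 ± 0.34). Within replicates the NK medians were −0.61 and −1.15 and the inflammasome medians 0.67 and 1.26. Without the second HFD + L-NAME library the inflammasome median was 0.75, without the second chow library the neutrophil median was 1.80 and the NK median −0.56, and without the first chow library the neutrophil median was 5.12.

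In classical monocyte-like cells, none of the genes named here passed edgeR, and they were chosen after their values were seen. Il1b, which encodes the cytokine interleukin-1 beta, was at 239 and 168 CPM against 58.3 and 54.2 in chow (log2 fold change 1.86 ± 0.27, SE, n = 2 and 2; edgeR adjusted p = 0.0926), with 2.03 and 1.62 within replicates. Gab1, an adaptor of growth-factor and cytokine receptors, was at 212 and 178 against 39.8 and 48.9 (2.13 ± 0.26; adjusted p = 0.0574; 2.40 and 1.85 within replicates). Ccl7, a chemokine that draws monocytes, was at 181 and 207 against 67.1 and 71.0 (1.49 ± 0.24; adjusted p = 0.143), and Cd14, the co-receptor for lipopolysaccharide, had 1.11 ± 0.30. Lower were Slamf7, a receptor of the SLAM family (−2.01 ± 0.30; adjusted p = 0.0926), and Ciart, a repressor within the circadian clock, at 10.3 and 6.16 against 44.2 and 41.0 (−2.29 ± 0.33; adjusted p = 0.0926; −2.05 and −2.65 within replicates). edgeR passed 0 of 12,001 genes in these cells and 132 with the replicate number as a block, which leaves 1 residual degree of freedom. An unadjusted p under 0.05 was found for 485 genes, a smaller share than the 0.05 that unchanged genes alone would give. DESeq2 passed 10 higher and 3 lower genes, with adjusted p = 4.17e-08 for Gab1, 1.76e-05 for Il1b and 0.00106 for Ccl7 and Ciart.

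**Figure D2:**
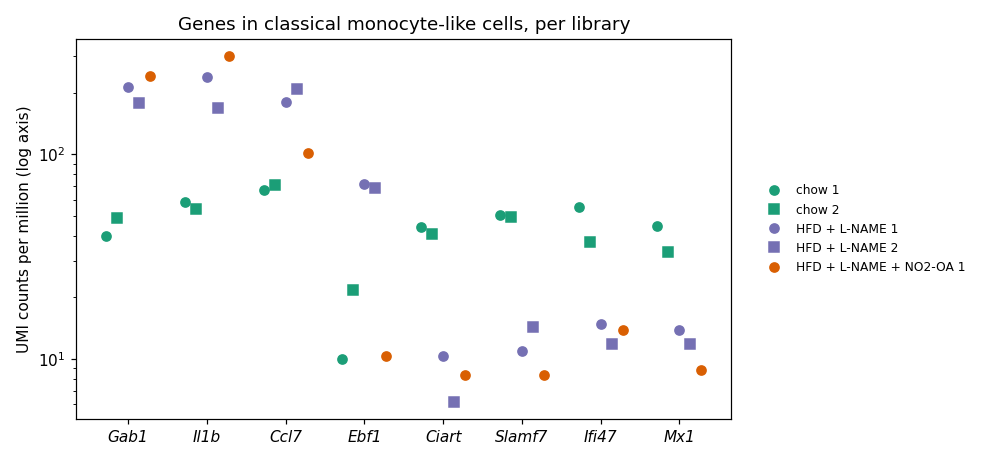
UMI CPM (log axis) of 8 genes in classical monocyte-like cells, with 1 point per library. Il1b lay at 58.3 and 54.2 in the chow libraries and at 239, 168 and 301 in the HFD + L-NAME and NO2-OA libraries.

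As a list, the inflammasome and alarmin genes rose in classical monocyte-like cells, with 21 of 24 members above 0 and a median of 0.63 (camera adjusted p = 6.66e-09; adjusted p = 0.582 with an estimated correlation). Of its members with most RNA, S100a6 had 0.14 ± 0.29, S100a4 0.17 ± 0.32 and S100a11 0.997 ± 0.31, and 2 members passed when adjusted over the list alone against 0 over all genes. Its median was 0.90 and 0.16 within replicates, 0.41 without the first chow library and 0.26 without the first HFD + L-NAME library. Interferon-stimulated genes, the antiviral response to interferons, fell, with 3 of 44 members above 0 and a median of −0.67 (adjusted p = 4.36e-17; adjusted p = 0.582 with an estimated correlation). Among them Ifi47 and Gbp2, interferon-induced GTPases, had −1.77 ± 0.32 and −1.42 ± 0.33, the antiviral Mx1 −1.57 ± 0.31 and Ifit3 −2.18 ± 0.58, while Ifi27l2a, Slfn5 and Trim30a, the members with most RNA, had −0.02 ± 0.28, −0.20 ± 0.26 and −0.17 ± 0.26. Adjusted over the list alone 5 members fell, and none did over all genes. The interferon median was −1.16 and −0.25 within replicates, −0.28 without the first and −1.08 without the second chow library, and −0.42 without the first HFD + L-NAME library. Circadian clock genes fell, with 2 of 12 members above 0 and a median of −0.54 (adjusted p = 4.15e-06; adjusted p = 0.582 with an estimated correlation; −0.50 and −0.59 within replicates). Ciart and Tef (−1.18 ± 0.36), an output factor of the clock, passed when adjusted over the list alone, while Bhlhe40 (−0.16 ± 0.45) and Cry1 (−0.41 ± 0.24), which have more RNA, did not. With the first chow library left out, Ifi27l2a, Slfn5, Trim30a and Bhlhe40 had 0.37, 0.09, 0.13 and 0.78 and S100a6 and S100a4 −0.08 and −0.20, the latter pair −0.20 and −0.06 without the first HFD + L-NAME library, and Ifi27l2a and Bhlhe40 0.05 and 0.01 without the second.

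Markers of other cells moved with these lists in classical monocyte-like cells, where camera called 4 marker lists higher and 2 lower. Non-classical monocyte markers had medians of −0.82 and −0.23 within replicates. Neutrophil markers had a median of 1.44 (camera adjusted p = 0.000134; adjusted p = 0.298 with an estimated correlation), with 0.87 and 0.27 within replicates, 0.87 without the second chow library and 0.63 without the first HFD + L-NAME library. B-cell markers had a median of 1.196 (adjusted p = 0.00106; adjusted p = 0.403 with an estimated correlation), with 1.73 and 0.57 within replicates and 2.01 without the second chow library. The B-marker median was 0.44 without the first chow library and its call was lost (adjusted p = 0.274). Ebf1, a transcription factor of B cells, was at 71.1 and 68.3 CPM against 10.0 and 21.7 (2.11 ± 0.35, n = 2 and 2; adjusted p = 0.143). At the finer clustering of resolution 2 the class fell into cluster 22, led by Vcan, with 4 and 0 chow, 301 and 11 HFD + L-NAME and 572 NO2-OA cells, and cluster 23, with 280 and 365, 61 and 103, and 43 cells.

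In non-classical monocyte-like cells, the patrolling monocytes of the vessel wall, markers of other cells were higher. The classical monocyte markers rose there, with 7 of 8 members above 0 and a median of 0.78 (adjusted p = 1.45e-05; adjusted p = 0.251 with an estimated correlation; 0.40 and 0.80 within replicates). Ccr2, the receptor that draws monocytes out of the marrow, had 1.95 ± 0.43 (2.66 and 0.92 within replicates), Chil3 0.99 ± 0.26 and Lyz2, lysozyme, 0.49 ± 0.25, with 2 members passing when adjusted over the list alone and 0 over all genes. These markers were not called in B-like (median 0.44; camera adjusted p = 0.267) or CD8 T-like cells (0.27; 0.0733). Within replicates their medians were still above 0 there, at 0.33 and 0.21 in B-like and 0.15 and 0.56 in CD8 T-like cells. CD4 T-like cells had −0.03 and 0.46, and the difference between classes was not tested for these markers. Neutrophil markers rose in the non-classical monocyte-like cells with a median of 1.39 (adjusted p = 0.0270; adjusted p = 0.479 with an estimated correlation; 0.00 and 2.85 within replicates; 2.47 without the first HFD + L-NAME library). Without any other library, fewer than 5 neutrophil markers were measured there. At resolution 2 the class fell into 2 clusters, of which cluster 29 held 1.12% and 97.4% of its cells in chow, 2.87% and 42.5% in HFD + L-NAME and 6.88% in NO2-OA. Gab1 had 1.60 ± 0.27 and Pecam1, an adhesion molecule, 1.10 ± 0.19. Interferon-stimulated genes fell in these cells too, with 5 of 39 members above 0 and a median of −0.45 (adjusted p = 1.05e-08; adjusted p = 0.483 with an estimated correlation; −0.56 and −0.30 within replicates). Its member Ifi27l2a had −0.16 ± 0.49, which was 0.57 without the first chow and 0.25 without the second HFD + L-NAME library. Irf8, a factor of monocyte development outside the list, had −0.96 ± 0.23. Without the first chow library the interferon median was −0.19, without the second −0.72, and without the first HFD + L-NAME library −0.71. edgeR passed 0 of 11,084 genes, 295 had an unadjusted p under 0.05, and DESeq2 passed 1.

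In T-like cells, lists of activation and cytotoxic genes were higher in the HFD + L-NAME libraries, as were neutrophil markers. In CD4 T-like cells, Batf, a factor of T-cell activation, had a log2 fold change of 1.46 ± 0.32 (n = 2 and 2; 1.58 and 1.23 within replicates), Runx2 1.10 ± 0.24, Ifng, which encodes interferon gamma, 1.44 ± 0.33 and the chemokine Ccl5 1.45 ± 0.36 (2.21 and 0.56 within replicates). The cytotoxic effector genes rose as a list, with 13 of 19 members above 0 and a median of 0.48 (camera adjusted p = 6.67e-05; adjusted p = 0.254 with an estimated correlation; 0.56 and 0.31 within replicates). Its members Ifng, Ccl5, Nkg7 (1.09 ± 0.32) and Tbx21, the master factor of type 1 helper cells (1.02 ± 0.30), rose when adjusted over the list alone and none did over all genes, while Srgn and Id2 had 0.49 ± 0.29 and 0.47 ± 0.33. The cytotoxic median was 0.31 without the first chow library, 0.23 without the first HFD + L-NAME library, when Id2 had −0.20, and 0.86 without the second HFD + L-NAME library. Lymphocyte activation and checkpoint genes rose with 15 of 17 members above 0 and a median of 0.47 (adjusted p = 9.43e-06; adjusted p = 0.254 with an estimated correlation; 0.40 and 0.59 within replicates), among them the co-stimulator Icos (0.72 ± 0.23), Tox (0.28 ± 0.27), Cd69 (0.47 ± 0.26) and Cd44 (0.32 ± 0.26). Without the second HFD + L-NAME library that median was 0.29 and the call was lost (adjusted p = 0.0745). The class joined cluster 1 and cluster 14, led by Tbc1d4 and with Icos and Ctla4, which held 8.98% and 18.1% of its cells in chow, 13.6% and 21.5% in HFD + L-NAME and 16.4% in NO2-OA. At resolution 2, cluster 7 held 2.80% and 2.31% of the class in chow, 52.8% and 7.18% in HFD + L-NAME and 76.5% in NO2-OA. Clusters were formed without integration, so different cells and a shift of expression across a whole library cannot be told apart here. Neutrophil markers rose with 6 of 6 members above 0 and a median of 2.40 (adjusted p = 7.04e-08; adjusted p = 0.437 with an estimated correlation; 1.29 and 3.05 within replicates), or 3.76 without the first and 1.57 without the second chow library.

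CD8 T-like cells showed the same list higher. Their cytotoxic effector genes rose with 18 of 20 members above 0 and a median of 0.42 (camera adjusted p = 1.12e-10; adjusted p = 0.482 with an estimated correlation; 0.84 and 0.09 within replicates). Gzmb, the killing protease granzyme B (1.78 ± 0.36), and Ifng (1.11 ± 0.24) passed when adjusted over the list alone against 0 over all genes, while Tbx21 had 0.73 ± 0.24, Nkg7 0.61 ± 0.34 and Ccl5 0.37 ± 0.48. That median was 0.21 without the first chow library, when Ccl5 had −0.25, and 0.69 without the second. The class joined cluster 2 and cluster 6, led by Ccl5, which held 25.1% and 35.5% of its cells in chow, 35.0% and 42.7% in HFD + L-NAME and 36.1% in NO2-OA, and at resolution 2 cluster 9 held 1.64% and 0.984%, 43.7% and 2.47%, and 66.1%. Neutrophil markers rose here too, with 7 of 7 members above 0 and a median of 1.93 (adjusted p = 1.50e-07; adjusted p = 0.272 with an estimated correlation; 0.72 and 3.45 within replicates). Their median was 3.46 without the first and 0.90 without the second chow library, and 2.96 without the first and 1.15 without the second HFD + L-NAME library. In CD4 T-like cells, interferon-stimulated genes rose with 37 of 45 members above 0 and a median of 0.50 (adjusted p = 2.38e-13; adjusted p = 0.449 with an estimated correlation; 0.93 and 0.00 within replicates), while classical monocyte-like cells had a median below 0 in both replicates. In the second replicate the CD4 T-like median (−0.003) was not above 0, so opposite changes were seen in the first replicate alone. The median over genes of the difference between these classes was 1.05 (adjusted p = 4.38e-18; adjusted p = 0.702 with an estimated correlation). The list was taken up for its opposite calls in the same data, so this is no separate test. Without the second HFD + L-NAME library the CD4 interferon median was 0.78, and without the first it was 0.13 and the call was lost (adjusted p = 0.216). Cell-cycle genes fell in CD4 T-like cells, with 4 of 23 members above 0 and a median of −0.41 (adjusted p = 9.43e-06; adjusted p = 0.254 with an estimated correlation; −0.40 and −0.42 within replicates). Birc5 (−2.59 ± 0.67) and Pclaf (−2.25 ± 0.63), which are made in dividing cells, were among 3 members that fell when adjusted over the list alone, while H2az1, Pcna and Mcm4, with more RNA, had 0.06 ± 0.25, −0.15 ± 0.24 and 0.74 ± 0.38. H2az1 had −0.15 without the first chow library, Mcm4 −0.13 without the first HFD + L-NAME library and Pcna 0.02 without the second.

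For heat-shock chaperones, which refold damaged proteins, the chow libraries lay apart from each other, and the replicates went opposite ways. Camera called the list higher at medians of 0.76 in B-like, 0.71 in CD4 T-like and 0.57 in CD8 T-like cells, with 18 of 18 members above 0 on voom values (camera adjusted p = 6.56e-05, 4.24e-06 and 3.60e-05; adjusted p = 0.787, 0.655 and 0.872 with an estimated correlation). On the edgeR fold changes, where the first chow library weighs more, the medians were 0.16, 0.30 and 0.16, with 10, 16 and 11 members above 0. Within replicates the medians were −0.54 and 1.92, −0.21 and 1.54, and −0.39 and 1.33. Hspa1a and Hspa1b, near-identical copies whose counts cannot be told apart with certainty, were at 2469 and 3389 CPM in the first chow library, at 6.32 and 4.03 in the second, and at 902 to 1341 in the HFD + L-NAME libraries. In CD4 T-like cells Hsp90ab1 and Hspa8 had 0.61 ± 0.48 and 0.52 ± 0.47, which were 1.69 and 1.54 without the first and −0.002 and −0.08 without the second chow library. In B-like cells Hsp90ab1 had 0.40 ± 0.63 and Hsp90aa1 −0.08 ± 0.89, while Hspa1a and Hspa1b had −0.35 ± 2.05 and −0.43 ± 2.21. With the first chow library left out, Hspa1a, Hspa1b and Hsp90aa1 had 7.26, 8.29 and 2.17, Hsp90ab1 had −0.29 without the second, and Hsp90aa1 0.25 without the second HFD + L-NAME library. Without the second chow library the chaperone medians were −0.60, −0.40 and −0.51, and without the first they were 2.14, 1.73 and 1.47. The B-like median was 0.53 without the first HFD + L-NAME library. Of genes chosen after their values were seen, Egr3, an early gene of B-cell receptor signalling, had −0.99 ± 0.25 and Lef1, a factor of immature lymphocytes, 0.81 ± 0.19.

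Red-cell RNA was higher in each tested class of the HFD + L-NAME libraries. In platelet-like cells Hbb-bs (ENSMUSG00000052305), an adult beta-globin, rose from 247 and 197 CPM in chow to 1358 and 1148 (log2 fold change 2.49 ± 0.40, n = 2 and 2; edgeR adjusted p = 0.0141; 2.45 and 2.54 within replicates). It was the 1 gene of 5728 that passed there, 54 had an unadjusted p under 0.05 and DESeq2 passed 2. It no longer passed without the second chow library (2.35; adjusted p = 0.203), with a mitochondrial share under 5% (3.49; 0.935), at least 500 genes (2.01; 0.0750), doublets kept (1.61; 1.00) or the 4 chow and HFD + L-NAME libraries alone (2.50; 0.270). It had 4.73 in cluster 9 alone and 2.00 in cluster 12 alone. Hba-a1 and Hba-a2, near-identical alpha-globin copies, had 0.44 ± 0.42 and 1.75 ± 0.37, and counts of Hbb-bs and its near copy Hbb-bt share this uncertainty. The erythroid markers rose as a list with medians of 0.82 in platelet-like, 1.09 in CD8 T-like, 1.90 in B-like, 2.14 in CD4 T-like, 2.20 in non-classical and 2.46 in classical monocyte-like cells (camera adjusted p of at most 1.90e-07; adjusted p between 0.0748 and 0.447 with an estimated correlation). Hbb-bs had 3.38 ± 0.48 in B-like, 3.96 ± 0.56 in CD4 T-like and 2.35 ± 0.35 in CD8 T-like cells. In non-classical monocyte-like cells the erythroid median was 0.67 and 4.19 within replicates, 3.72 without the first and 0.81 without the second HFD + L-NAME library. The platelet-like class joined cluster 9, with 66 and 207 chow and 74 and 1406 HFD + L-NAME cells and a median of 822 UMIs, and cluster 12, with 617 and 49 and 469 and 236 cells and a median of 4307 UMIs.

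**Figure D3:**
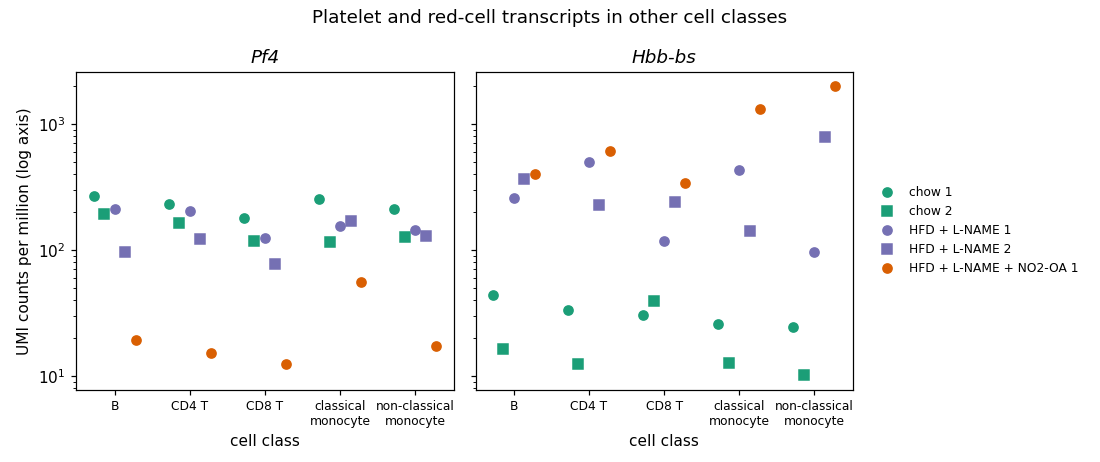
UMI CPM (log axis) of Pf4, a platelet gene, and of Hbb-bs in other cell classes, with 1 point per library. The NO2-OA library lies lowest for Pf4 in each class shown, and the chow libraries lie lowest for Hbb-bs.

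Across the tested classes, edgeR passed 0 genes for HFD + L-NAME against chow in B-like, CD8 T-like and CD4 T-like cells and over all cells. Genes with an unadjusted p under 0.05 numbered 210 of 16,981 in B-like, 219 of 15,064 in CD8 T-like, 286 of 14,448 in CD4 T-like cells and 600 of 20,504 over all cells. Unchanged genes alone would give a share of 0.05, and each of these counts lies below it. So do the counts above for platelet-like and monocyte-like cells. Counts for NO2-OA below lie under that share too, except against chow in classical monocyte-like cells. DESeq2 passed 4, 4, 5 and 46 genes. With the replicate number as a block edgeR passed 2, 32, 54 and 0. Without the first chow library, edgeR passed 6 genes in B-like, 72 in CD8 T-like, 149 in CD4 T-like, 4 in platelet-like, 259 in non-classical and 15 in classical monocyte-like cells and 3 over all cells. Without the second chow library it passed 0, 282, 66, 3, 96, 4 and 0. Without the first HFD + L-NAME library it passed 15, 5, 8, 14, 0, 7 and 0, and without the second 0, 17, 35, 1, 1, 24 and 0. In each of these fits the spread came from 1 pair of like libraries, and the lone library was assumed to vary like the other groups. Camera called 8 of 23 lists in B-like, 9 in CD8 T-like, 11 in CD4 T-like, 10 of 22 in non-classical and 7 of 23 in classical monocyte-like cells, 3 of 19 in platelet-like cells and 9 of 23 over all cells, and 0 with an estimated correlation in each. With the second HFD + L-NAME library left out it called 4 lists in B-like, 1 in platelet-like and 11 in classical monocyte-like cells, and with the first left out 5 in CD8 T-like and 7 in platelet-like cells.

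**Figure D4:**
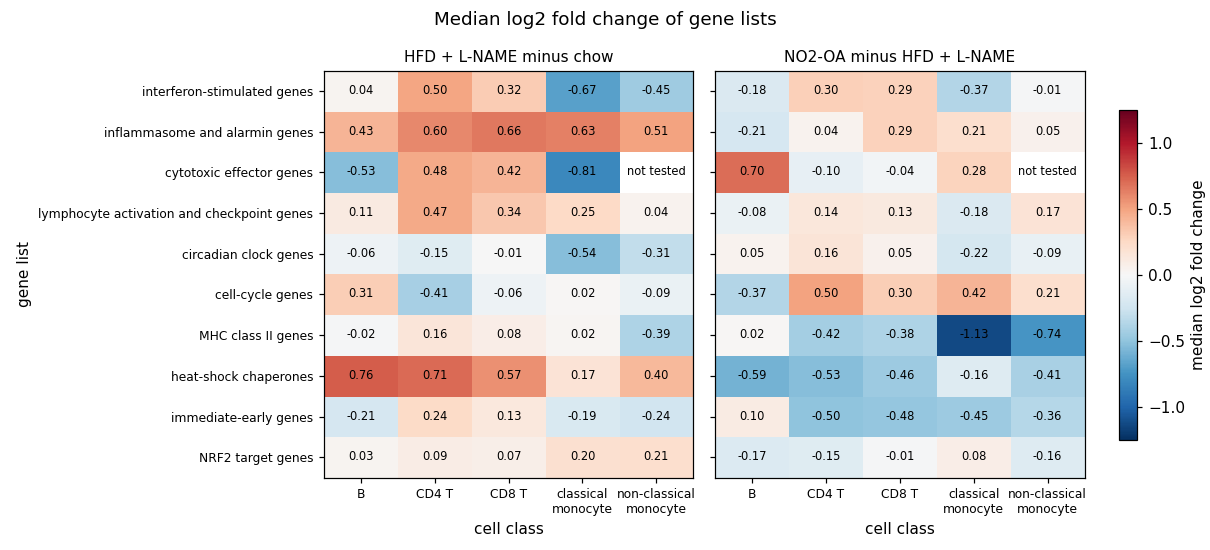
Median log2 fold change of 10 gene lists (colour and number) in 5 cell classes, for HFD + L-NAME against chow and for NO2-OA against HFD + L-NAME. Interferon-stimulated genes had a median of −0.67 in classical monocyte-like and 0.50 in CD4 T-like cells in the first comparison.

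The comparison of NO2-OA with HFD + L-NAME asks how the cells differed when the nitrated fatty acid was given on top of the regimen. Platelet transcripts were far lower in the NO2-OA library. Its platelet-like cells made up 0.762% of cells (exact 95% binomial interval 0.617% to 0.929%) against 5.08% and 22.9% (log2 ratio −4.20 ± 1.37, SE, n = 1 and 2; edgeR adjusted p = 0.192). In CD4 T-like cells, RNA of the platelet genes Pf4, a platelet chemokine, Clec1b, a platelet activating receptor, Gp9, part of the von Willebrand factor receptor, and Ppbp had −3.43 ± 0.44, −3.67 ± 0.44, −3.43 ± 0.47 and −2.88 ± 0.70 (adjusted p = 0.0886 for Pf4 and Clec1b and 0.0951 for Gp9). Pf4 had −3.01 ± 0.43 in CD8 T-like, −3.00 ± 0.55 in B-like, −2.98 ± 0.40 in non-classical and −1.55 ± 0.46 in classical monocyte-like cells and −4.08 ± 0.79 over all cells. These genes were chosen after their values were seen, and the single NO2-OA library was assumed to vary like the other groups. Without the second HFD + L-NAME library the platelet-like log2 ratio was −2.74.

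The platelet markers fell as a list with 0 of 9 members above 0 in each of 5 classes and over all cells. Their medians were −3.05 in CD4 T-like, −2.64 in CD8 T-like, −2.66 in B-like, −2.45 in non-classical and −1.15 in classical monocyte-like cells and −3.60 over all cells (camera adjusted p of at most 1.94e-10; adjusted p = 0.457, 0.554, 0.356, 0.222, 0.233 and 0.331 with an estimated correlation). Adjusted over the list alone, 9 members fell in CD4 T-like, 7 in CD8 T-like and 9 in B-like cells, against 0 over all genes. Against each HFD + L-NAME library in turn the median was −3.16 and −2.74 in CD4 T-like cells and −2.99 and −2.0004 in B-like cells. In platelet-like cells Mpc1, the mitochondrial pyruvate carrier, had −2.11 ± 0.62 (n = 1 and 2), where the median of all 5728 tested genes was −0.29. The NO2-OA library held 58 cells of cluster 9 and 38 of cluster 12.

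NK-like cells and cytotoxic transcripts were higher in the NO2-OA library, whose share of platelet-like cells was lower. NK-like cells made up 2.04% (1.80% to 2.30%) against 0.712% and 0.628% (log2 ratio 1.60 ± 0.48, n = 1 and 2; edgeR adjusted p = 0.192), CD4 T-like cells 21.5% against 12.5% and 5.05% (1.29 ± 0.71; adjusted p = 0.365), and CD8 T-like cells had 1.12 ± 0.73. For both T-like classes the difference was smaller from the first HFD + L-NAME library than from the second. None of the 10 classes passed, and 2 had an unadjusted p under 0.05. Over all cells the NK markers rose with 8 of 8 members above 0 and a median of 1.09 (camera adjusted p = 1.18e-11; adjusted p = 0.331 with an estimated correlation; 1.05 and 1.18 against each HFD + L-NAME library). Gzma, the protease granzyme A, had 1.56 ± 0.39, the receptor Klre1 1.09 ± 0.26 and Klrd1 0.75 ± 0.32. Stk39, a kinase gene outside the marker list, had 1.43 ± 0.24. The cytotoxic effector genes rose over all cells with 19 of 20 members above 0 and a median of 0.86 (adjusted p = 8.62e-12; adjusted p = 0.498 with an estimated correlation), with Ccl5 at 1.24 ± 0.56. That median was 0.56 and 1.09 against each HFD + L-NAME library, and 0.54 without the second.

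In T-like cells, immediate-early genes, the first transcripts after stimulation, fell in the NO2-OA library. The list had 0 of 20 members above 0 with medians of −0.50 in CD4 and −0.48 in CD8 T-like cells (camera adjusted p = 1.20e-13 and 5.01e-13; adjusted p = 0.301 and 0.812 with an estimated correlation). Against each HFD + L-NAME library the medians were −0.60 and −0.46 in CD4 and −0.61 and −0.33 in CD8 T-like cells. The fall was not particular to T-like cells. These medians were −0.36 and −0.47 in classical and −0.44 and −0.26 in non-classical monocyte-like cells. They were −0.69 and −1.47 in platelet-like cells, while B-like cells went both ways (−0.06 and 0.26). At resolution 2, cluster 7 held 76.5% of CD4 T-like cells in NO2-OA against 52.8% and 7.18% in HFD + L-NAME, and cluster 9 held 66.1% of CD8 T-like cells against 43.7% and 2.47%. B-cell markers fell in the T-like cells too, with medians of −0.83 in CD4 and −0.62 in CD8 T-like cells (adjusted p = 0.0116 and 0.0162; adjusted p = 0.481 and 0.590 with an estimated correlation), and with −0.66 and −0.68, and −0.52 and −0.44, against each HFD + L-NAME library. With the replicate number as a block these 2 calls were lost (−0.37 and −0.34; adjusted p = 0.117 and 0.382). Fos, a subunit of the AP-1 factor, had −1.29 ± 0.37 in CD4 and −1.31 ± 0.34 in CD8 T-like cells (n = 1 and 2), Klf2, a factor of resting T cells, −0.63 ± 0.36 and −0.56 ± 0.37, and Junb −0.29 ± 0.41 and −0.21 ± 0.36. Heat-shock chaperones fell with 0 of 18 members above 0 at medians of −0.59 in B-like, −0.53 in CD4 and −0.46 in CD8 T-like cells (adjusted p = 0.00462, 0.00216 and 0.000932; adjusted p = 0.914, 0.749 and 0.918 with an estimated correlation). In CD4 T-like cells Hsp90ab1 had −0.52 ± 0.60. Against each HFD + L-NAME library those medians were −0.93 and −0.32, −0.70 and −0.32, and −0.64 and −0.33. Without the first HFD + L-NAME library the chaperone median was −0.32 in CD4 T-like cells, and it was −0.32 in B-like cells, where the call was lost (adjusted p = 0.0563), against −0.93 without the second. Cell-cycle genes rose in CD4 T-like cells with 17 of 23 members above 0 and a median of 0.50 (adjusted p = 2.08e-06; adjusted p = 0.301 with an estimated correlation; 0.39 and 0.79 against each library). Birc5 (3.21 ± 0.71) and Pclaf (2.76 ± 0.69) passed when adjusted over the list alone, while H2az1, Pcna and Mcm4 had −0.05 ± 0.31, −0.18 ± 0.29 and 0.38 ± 0.46, and Mcm4 had −0.15 without the second HFD + L-NAME library.

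Targets of NRF2, the stress factor that electrophilic fatty acids can activate, were not higher in lymphocytes of the NO2-OA library. The list fell with 6 of 23 members above 0 and a median of −0.15 in CD4 T-like cells and 5 of 24 and −0.17 in B-like cells (camera adjusted p = 0.00216 and 0.00700; adjusted p = 0.301 and 0.520 with an estimated correlation). Fth1 and Ftl1, the ferritin chains that store iron, had −0.59 ± 0.36 and −0.54 ± 0.36 in CD4 T-like and −0.42 ± 0.35 and −0.46 ± 0.32 in B-like cells (n = 1 and 2), and Prdx1 −0.05 ± 0.29 in CD4 T-like cells, or 0.04 without the first HFD + L-NAME library. In CD8 T-like cells 11 of 24 members lay above 0, with a median of −0.01 and a mean of −0.24 (adjusted p = 0.0400; adjusted p = 0.812 with an estimated correlation), and Srxn1, which repairs oxidised peroxiredoxins, had −3.36 ± 0.78. Non-classical monocyte-like cells had 4 of 23 above 0 and a median of −0.16 (adjusted p = 0.0252; adjusted p = 0.989 with an estimated correlation), and in classical monocyte-like cells the list was not called (14 of 23, median 0.08; camera adjusted p = 0.280). Without the first HFD + L-NAME library the calls were lost in CD4 T-like (adjusted p = 0.228), B-like (0.224), CD8 T-like (0.758, median −0.11) and non-classical monocyte-like cells (0.507, median −0.08), and without the second the CD8 median was −0.24. Against each HFD + L-NAME library the medians were −0.22 and −0.16 in CD4 T-like and −0.15 and −0.21 in B-like cells.

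In classical monocyte-like cells, genes of antigen presentation by MHC class II were lower in the NO2-OA library, as they were in other classes. MHC class II genes fell with 1 of 12 members above 0 and a median of −1.13 (camera adjusted p = 4.69e-09; adjusted p = 0.519 with an estimated correlation; −1.14 and −0.91 against each HFD + L-NAME library). In other classes its medians against each library were −0.40 and −0.39 in CD4 T-like and −0.33 and −0.29 in CD8 T-like cells. They were −0.71 and −1.29 in platelet-like and −0.18 and −0.78 in non-classical monocyte-like cells, and −0.12 and 0.14 in B-like cells. In classical monocyte-like cells Cd74, the invariant chain, had −1.12 ± 0.37, H2-Aa −1.57 ± 0.59 and H2-Ab1 −1.29 ± 0.51 (n = 1 and 2), while Ctss, the protease cathepsin S, had 0.13 ± 0.29. B-cell markers fell in the same cells with 0 of 8 members above 0 and a median of −2.15 (adjusted p = 3.95e-12; adjusted p = 0.214 with an estimated correlation; −1.74 and −2.26 against each library), with 7 members falling when adjusted over the list alone. Bank1 had −2.11 ± 0.60 and Pax5 −2.65 ± 0.75, and Ebf1, a B-cell gene outside the list, −2.75 ± 0.46. Non-classical monocyte markers fell with 0 of 9 members above 0 and a median of −1.04 (adjusted p = 6.58e-11; adjusted p = 0.214 with an estimated correlation; −0.67 and −1.64 against each library), among them Nr4a1, which drives that fate (−0.93 ± 0.33), and Ace (−1.97 ± 0.62). That median was −1.72 without the first and −0.67 without the second HFD + L-NAME library. Ccl7 had −0.93 ± 0.30 in classical monocyte-like cells.

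In B-like cells, Jchain, the joining chain of secreted antibodies, was at 149 CPM in the NO2-OA library against 14.4 and 4.73 in HFD + L-NAME and 50.1 and 18.7 in chow (log2 fold change 3.95 ± 0.76 against HFD + L-NAME, n = 1 and 2). The B-like class differed in make-up, with cluster 0 holding 61.9% of it in the NO2-OA library, 44.5% and 30.7% in HFD + L-NAME and 37.2% and 45.1% in chow. Cluster 3 held 14.5%, 14.6% and 35.7%, and 13.9% and 14.5%, cluster 5 0.752%, 13.8% and 4.14%, and 21.4% and 11.8%, and cluster 11 5.11%, 4.91% and 17.6%, and 4.23% and 5.85%. Cluster 5 carried platelet transcripts, with a platelet-marker score of 1.36 beside its B-cell score of 3.59. Its low share in the NO2-OA library may thus follow the lower platelet transcripts there, and a lower share of 1 cluster raises those of the others. The plasma-cell markers, of which Jchain is 1, went both ways, with 4 of 7 members above 0 and a median of 0.19 (camera adjusted p = 0.00553; adjusted p = 0.356 with an estimated correlation; 0.48 and −0.58 against each library), −0.03 on the edgeR fold changes, −0.58 without the first and 0.48 without the second HFD + L-NAME library. edgeR passed 0 genes for NO2-OA against HFD + L-NAME in each class. Genes with an unadjusted p under 0.05 numbered 270 in B-like, 214 in CD8 T-like, 282 in CD4 T-like, 204 in platelet-like, 221 in non-classical and 216 in classical monocyte-like cells and 587 over all cells. DESeq2 passed 39, 24, 37, 0, 5, 3 and 141 in the same order, and edgeR with the replicate number as a block 77, 65, 91, 3, 4, 25 and 0. Without the first chow library edgeR passed 0, 32, 85, 0, 44, 1 and 0 genes, and without the second 0, 62, 70, 0, 31, 0 and 53. Without the first HFD + L-NAME library it passed 9, 8, 18, 0, 0, 28 and 0, and without the second 17, 30, 44, 0, 0, 0 and 0. Camera called 8 of 23 lists in B-like, 9 in CD8 T-like, 10 in CD4 T-like, 11 in classical monocyte-like cells and 13 over all cells, 5 of 22 in non-classical monocyte-like cells and 2 of 19 in platelet-like cells, and 0 with an estimated correlation in each. With the first HFD + L-NAME library left out it called 4 lists in B-like cells, with the second left out 8 in non-classical monocyte-like and 0 in platelet-like cells, and with either chow library left out 1 in platelet-like cells.

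Against chow, edgeR passed 6 higher and 1 lower gene in classical monocyte-like cells of the NO2-OA library, on the assumption that this single library varied like the other groups. It lies in the first set alone, while chow pools both, so these genes may follow the set. An unadjusted p under 0.05 was found for 787 genes, and DESeq2 passed 33 higher and 24 lower. Among those of edgeR, Il1b had a log2 fold change of 2.42 ± 0.30 (n = 1 and 2; edgeR adjusted p = 0.0307), Gab1 with 2.44 ± 0.29 (0.0307), the metal-binding Mt2 with 4.38 ± 0.55 (0.0307), the neutrophil chemokine Cxcl1 with 2.50 ± 0.37 (0.0490) and Lamc1, a laminin chain, with 3.18 ± 0.45 (0.0490), while Slamf7 was lower (−2.57 ± 0.38; 0.0490). None of the 7 genes passed with doublets kept. Against the first chow library the same cells had medians of 1.95 for neutrophil and 3.76 for erythroid markers, and 572 of them lay in cluster 22 of resolution 2 against 4 and 0 in chow. With the replicate number as a block 185 genes passed. Counts without 1 library were 101 and 34 when a chow library was left out and 95 and 66 when an HFD + L-NAME library was. In the other classes edgeR passed 0 genes, while 304 in B-like, 447 in CD8 T-like, 558 in CD4 T-like, 212 in platelet-like and 431 in non-classical monocyte-like cells and 524 over all cells had an unadjusted p under 0.05. DESeq2 passed 87, 54, 82, 0, 22 and 126, and edgeR with the block 117, 155, 188, 21, 4 and 3. Without the first chow library edgeR passed 4, 137, 430, 1, 373 and 3 in those classes, without the second 5, 299, 210, 0, 147 and 75, without the first HFD + L-NAME library 61, 69, 112, 0, 0 and 0, and without the second 47, 88, 127, 0, 2 and 2. No gene passed both this test and that of HFD + L-NAME against chow, since the latter passed 0 genes in classical monocyte-like cells.

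A last comparison asked whether NO2-OA moved genes back from their change on the regimen. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at −0.403 in B-like, −0.412 in CD8 T-like, −0.403 in CD4 T-like and −0.0930 in platelet-like cells. Both comparisons share the HFD + L-NAME libraries with opposite sign, and simulations of unchanged groups gave −0.407, −0.499, −0.501 and −0.195. The simulations drew libraries independently, although deviations from the group mean correlated between chow and HFD + L-NAME by replicate number (0.351, 0.144, 0.191 and 0.319, and 0.395 over all cells). A shared set effect cancels between HFD + L-NAME and chow but counts as spread in the simulations, so their values can be too negative and do not rule out a reversal. Covariances were −0.0786, −0.0818, −0.0911 and −0.0603 against −0.111, −0.137, −0.147 and −0.146 in the simulations. Over all cells the correlation of −0.481 was more negative than the simulated −0.417, while the covariance of −0.171 was not (−0.182). Both were more negative there without the first HFD + L-NAME library (−0.766 and −0.605 against −0.589 and −0.370) and without the second chow library (−0.492 and −0.225 against −0.344 and −0.183), and neither without the second HFD + L-NAME library (−0.374 and −0.114 against −0.582 and −0.359) or without the first chow library (−0.248 and −0.117 against −0.339 and −0.182). Opposite signs were found for 69.0%, 67.0%, 65.8% and 51.7% of genes in the 4 classes, against 63.4%, 65.3%, 65.5% and 58.2% in the simulations. Without the first chow library the correlations were −0.219, −0.250, −0.259 and 0.0101 and the covariances −0.0565, −0.0658, −0.0789 and 0.0112, against −0.330, −0.411, −0.415 and −0.139 and −0.111, −0.136, −0.147 and −0.153 in the simulations. Without the second the platelet-like values were −0.211 and −0.132, against −0.179 and −0.139. Without the first HFD + L-NAME library, where the shared term rests on 1 library, the correlations were −0.694, −0.715, −0.700 and −0.296 and the covariances −0.273, −0.291, −0.311 and −0.259, against −0.583, −0.706, −0.707 and −0.313 and −0.229, −0.333, −0.358 and −0.288. In that setting both B-like values were thus more negative than the simulations, while without the second HFD + L-NAME library neither was (−0.433 and −0.0891 against −0.570 and −0.217). Platelet-like values there were −0.160 and −0.127, against −0.310 and −0.285. Leaving out 1 library also unbalances the sets, and a set effect alone then makes both values more negative without the first HFD + L-NAME or the second chow library. A reversal was therefore left undecided in the 4 classes and over all cells.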

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

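All tests of explanations below were chosen only after the result was seen, except the marker test for peritoneal macrophages.

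Platelet transcripts were lower in the other cell classes of the NO2-OA library. Platelet RNA dissolved in the suspension, as the whole cause, is argued against, because B-like cells without a platelet-marker UMI were at least 2.47 times as many in the chow libraries as a Poisson spread of dissolved RNA gives. Platelets attached to cells or sharing their droplets remain a candidate explanation, since cells with at least 10 platelet-marker UMIs held at least 24.6% of these UMIs in B-like, CD4 T-like and CD8 T-like cells of each other library, and 7.80% in the fewer regulatory T-like cells of the second chow library. An effect of NO2-OA on platelets stays open, with platelet-like cells at 0.762% of that library and at 2.64% or more of the others, because 1 library cannot part the treatment from its preparation.

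Haemoglobin transcripts were higher than in both chow libraries in each tested class of the HFD + L-NAME libraries and, outside platelet-like cells, of the NO2-OA library, and barcodes under 200 genes, which the comparisons leave out, made up 4.03% and 4.15% of the HFD + L-NAME and 7.02% of the NO2-OA barcodes, above the chow libraries (1.011% at most). Red-cell RNA dissolved in the suspension is a candidate source for part of it, since B-like, CD4 T-like and CD8 T-like cells without a haemoglobin UMI were at most 1.34 times the Poisson number in these 3 libraries, though 2.77 times among the 44 regulatory T-like cells of the second HFD + L-NAME library. Cells with at least 10 haemoglobin UMIs held 3.76% to 74.4% of these UMIs in the 3 former classes, so red cells sharing droplets stay open as well. More red cells in the blood of animals on the regimen may have brought it, since the lowest share of such barcodes was 3.98 times the highest chow share. Incomplete red-cell lysis would give the same, so the 2 cannot be told apart.

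An unnamed cluster of macrophage-like cells, cluster 21, made up 4.31% of the second HFD + L-NAME library, above the limit of a count of 0. It held 309 cells there, 99 in the second chow library, and 0 in each of the other 3. The regimen as the whole cause is argued against, since a count of 0 in the first HFD + L-NAME library allows at most 0.0281%, below the 1.02% of the second chow library. Peritoneal macrophages carried into the preparation are a candidate source, since 8 of 10 genes listed for them, among them Gata6 and Timd4, were at least 4 times as high as in both monocyte-like classes and detected in at least 10% of the cluster's cells. Of the listed genes, 3 were also expressed in monocyte-like cells, and no sort would have removed such cells.

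Gene lists with opposite calls in a pair of classes were compared by camera on the difference between the classes. Of 638 differences compared, 22 joined opposite calls. In 16 of these the medians also lay on opposite sides of 0 in both library pairs, which are the replicates for HFD + L-NAME against chow and the single NO2-OA library against each HFD + L-NAME library for the other. An adjusted p under 0.05 was also required of them, and the opposite calls came from the same data. Their adjusted p of at most 0.00938 is thus no separate test, and it was at least 0.470 with an estimated correlation. For HFD + L-NAME against chow, the median difference of the cytotoxic effector genes was −0.95 between B-like and CD8 T-like and −0.46 between B-like and CD4 T-like cells. In the B-like cells the markers of CD8 and CD4 T cells fell as well, with medians of −0.77 and −0.63 (camera adjusted p = 0.000395 and 0.0488; adjusted p = 0.464 for both with an estimated correlation; −0.37 and −1.84, and −0.14 and −1.39 within replicates), and both rose to a median of 1.20 for NO2-OA (adjusted p = 1.16e-05 and 0.000186; adjusted p = 0.356 with an estimated correlation). For HFD + L-NAME the call of the CD4 markers was lost without any 1 library (medians −0.76 and −0.58 without the first and second chow, −1.28 and −0.01 without the first and second HFD + L-NAME library), and that of the CD8 markers without the second chow (−0.64; adjusted p = 0.205) or HFD + L-NAME library (−0.37; 0.114), against −1.36 without the first chow and −1.46 without the first HFD + L-NAME library. For NO2-OA the CD4 median was 0.74 without the second HFD + L-NAME library. Both marker lists hold Cd3e, Cd3d and Trac, so their medians are not separate results. T-cell RNA in droplets of B-like cells was not tested and stays open for the B-like side. Immediate-early genes differed by −0.45 between B-like and CD4 T-like and by 0.50 between CD4 T-like and non-classical monocyte-like cells, and cell-cycle genes by 0.96 between B-like and CD4 T-like cells. For NO2-OA against HFD + L-NAME, interferon-stimulated genes differed by −0.52 and −0.56 between B-like and CD8 or CD4 T-like cells, and by 0.69 and 0.76 between CD8 or CD4 T-like and classical monocyte-like cells. Cell-cycle genes differed by −0.93, −0.81 and −0.41 between B-like and CD8 T-like, CD4 T-like and classical monocyte-like cells. Ribosomal protein genes differed by −0.22, −0.40, −0.40 and −0.18 between B-like, CD8 T-like, CD4 T-like or non-classical monocyte-like and classical monocyte-like cells.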

How the results depend on the processing

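Alternatives added after the data were seen were the B-like cells without a cluster, the single platelet clusters, the shares of lymphocytes and monocytes, the list tests with a block or without 1 library, the list medians from edgeR, and the reversal without 1 library. Counts below are genes passing the threshold in B-like, CD8 T-like, CD4 T-like, platelet-like, non-classical and classical monocyte-like cells and over all cells, where they moved by over 1.5 times. "Regimen" stands for HFD + L-NAME against chow, "treatment" for NO2-OA against HFD + L-NAME. Except where the construction is given, the cause was not tested.

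With DESeq2 the counts were 4, 4, 5, 2, 1, 13 and 46 for the regimen, 39, 24, 37, none in platelet-like, 5, 3 and 141 for the treatment, and 87, 54, 82, none in platelet-like, 22, 57 and 126 for NO2-OA against chow. DESeq2 size factors in edgeR gave 1 in classical monocyte-like cells for the regimen. With no filter the counts were 1, 16, 36, 2, 44 and 95 for the regimen, 1, 47 and 65 in lymphocytes and 30 and 31 in monocytes for the treatment, and 6, 131, 199, 97 and 273 for NO2-OA against chow. Clusters from centred expression gave 32 in CD8 T-like, 53 in CD4 T-like and 1 in classical monocyte-like cells for the regimen, 41 and 47 in T-like cells for the treatment, and 71, 80 and 16 (12 higher and 4 lower) for NO2-OA against chow. A mitochondrial share under 5% gave 0 in platelet-like cells for the regimen, 4 in CD4 T-like cells for the treatment, and 6 in CD8 T-like, 4 in CD4 T-like and 4 in classical monocyte-like cells for NO2-OA against chow. At least 500 genes per cell, and the 4 chow and HFD + L-NAME libraries alone, which leave fewer cells or libraries, each gave 0 in platelet-like cells for the regimen. Doublets kept gave 0 in platelet-like and 3 in non-classical monocyte-like cells for the regimen, and 4 in CD8 T-like, 3 in non-classical and 0 in classical monocyte-like cells for NO2-OA against chow. Resolution 2 gave 4 in classical monocyte-like cells for NO2-OA against chow. Equal numbers of cells gave 3 in platelet-like and 2 in classical monocyte-like cells for the regimen, 6 in CD4 T-like and 2 in non-classical monocyte-like cells for the treatment, and 11, 2 and 11 in CD4 T-like, non-classical and classical monocyte-like cells for NO2-OA against chow. Thinned counts gave 1 in classical monocyte-like cells for the regimen, 1 in CD4 T-like cells for the treatment, and 1 and 4 in these classes for NO2-OA against chow. Platelet cluster 12 alone and cluster 9 alone each gave 2 for the regimen, and cluster 9 gave 14 for NO2-OA against chow.

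The replicate number as a block gave 2, 32, 54, 16 and 132 in B-like, T-like, platelet-like and classical monocyte-like cells for the regimen, 77, 65, 91, 3, 4 and 25 for the treatment, and 117, 155, 188, 21, 4, 185 and, over all cells, 3 for NO2-OA against chow. Libraries with 1 number correlated in their deviations from the group means at 0.351 in B-like and 0.101 in classical monocyte-like cells, and with 2 pairs this does not show pairing. With the block, 0 lists were called in platelet-like cells for the treatment, Hspa1a and Hspa1b turned to 2.87 and 3.30 and Hsp90aa1 to 0.58 in B-like cells, Ifi27l2a to 0.014 and Bhlhe40 to 0.0012 in classical monocyte-like cells, and H2az1 to 0.057 in CD4 T-like cells for the treatment.

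Leaving out 1 library, where the spread comes from fewer libraries, gave between 0 and 15, 5 and 282, 8 and 149, 1 and 14, 0 and 259, 4 and 24, and 0 and 3 genes for the regimen, 0 and 17, 8 and 62, 18 and 85, 0 and 44, 0 and 28, and 0 and 53 for the treatment outside platelet-like cells, and 4 and 61, 69 and 299, 112 and 430, 0 and 1, 0 and 373, 34 and 101, and 0 and 75 for NO2-OA against chow. Called gene lists numbered 0 with an estimated correlation and 0 with fry in each class and both comparisons. Of the marker lists, fry called the erythroid markers in platelet-like cells (adjusted p = 0.0140) and the classical monocyte markers in non-classical monocyte-like cells (0.0402) for the regimen. Without 1 library they ran from 4 to 10 in B-like, 5 to 9 in CD8 T-like, 1 to 7 in platelet-like and 8 to 11 in classical monocyte-like cells for the regimen, and from 4 to 9 in B-like, 0 to 3 in platelet-like and 4 to 8 in non-classical monocyte-like cells for the treatment. The correlation of both comparisons ran from −0.694 to −0.219 in B-like, −0.715 to −0.250 in CD8 T-like, −0.700 to −0.259 in CD4 T-like and −0.296 to 0.0101 in platelet-like cells, and the covariance from −0.273 to −0.0565, −0.291 to −0.0658, −0.311 to −0.0789 and −0.259 to 0.0112.

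Named genes with a small or widely spread change turned in sign. Without 1 library, values in classical monocyte-like cells ran from −0.33 to 0.37 for Ifi27l2a, −0.45 to 0.095 for Slfn5, −0.42 to 0.13 for Trim30a, −0.72 to 0.78 for Bhlhe40, −0.20 to 0.41 for S100a6 and −0.205 to 0.70 for S100a4, and in non-classical ones from −0.762 to 0.571 for Ifi27l2a, which turned to 0.0454 with centred expression. In classical ones Ifi27l2a turned to 0.012 with centred expression and 0.0022 when thinned. In CD4 T-like cells they ran from −0.20 to 0.92 for Id2, −0.15 to 0.30 for H2az1, −0.33 to 0.017 for Pcna and −0.13 to 1.26 for Mcm4, and from −0.15 to 1.25 for Mcm4 and −0.155 to 0.0397 for Prdx1 for the treatment. With a mitochondrial share under 5%, H2az1 turned to −0.0025 for the regimen and 0.051 for the treatment. Ccl5 ran from −0.25 to 1.46 in CD8 T-like cells. In B-like cells Hspa1a ran from −1.33 to 7.26, Hspa1b from −1.41 to 8.29, Hsp90ab1 from −0.29 to 1.85 (−0.0023 to 1.69 in CD4 T-like cells, Hspa8 there from −0.0753 to 1.54) and Hsp90aa1 from −0.90 to 2.17. The medians of heat-shock chaperones ran from −0.60 to 2.14 in B-like, −0.40 to 1.73 in CD4 T-like and −0.51 to 1.47 in CD8 T-like cells, lowest without the second and highest without the first chow library. The median of plasma-cell markers in B-like cells for the treatment ran from −0.584 to 0.480 and was −0.0267 from edgeR.

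Hbb-bs in platelet-like cells no longer passed with a mitochondrial share under 5% (3.49; adjusted p = 0.935), at least 500 genes (2.01; 0.0750), doublets kept (1.61; 1.00), 4 libraries (2.50; 0.270) and without the second chow library (2.35; 0.203). Of the values of named genes under the alternatives fixed beforehand, 1681 kept their direction and their side of the threshold, 206 newly passed with their direction kept, 22 no longer passed and 37 turned in sign. Of the list values with a block, without 1 library or, with no test, from edgeR, 317 kept both, 17 were no longer called and 5 turned. These counts overstate stability, since the genes and lists described were chosen with the alternatives in view and less steady ones were left out. Few of the named genes passed at first, so keeping their side of the threshold mostly meant staying short of it. Over all 192 calls of a list in a class, described or not, 754 values kept both, 159 were no longer called and 40 turned, with 105 calls lost and 37 turned at least once. Over the 4 members with the highest mean of each, 10,758 values kept both, 257 newly passed, 5 no longer passed and 539 turned, in 296 of 747 pairs of a gene and a class in a comparison. Of these pairs only Hbb-bs in platelet-like cells had passed at first, so no other pair could lose a call. The 10 named class shares stayed on their side of the threshold in 10 alternatives, as did the 7 and 6 that the 2 smaller totals leave. The self-test recovered 15% of simulated 4-fold changes in shares for the regimen and 6.5% for the treatment.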

Other observations

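Genes of cholesterol synthesis, which cells raise when sterols run short, fell in non-classical monocyte-like cells of the HFD + L-NAME libraries, with 4 of 20 members above 0 and a median log2 fold change of −0.32 (camera adjusted p = 3.30e-05; adjusted p = 0.483 with an estimated correlation; −0.34 and −0.41 within replicates). Srebf2, the master factor of this pathway, had −0.81 ± 0.20 (n = 2 and 2). The median was −0.21 without the first and −0.53 without the second chow library and −0.20 without the second HFD + L-NAME library. Fatty-acid handling and oxidation genes were not called by camera in any tested class or over all cells in either comparison, with a median of 0.08 and a mean of −0.11 in classical monocyte-like cells for HFD + L-NAME against chow (15 of 25 members above 0; adjusted p = 0.895).

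Nitric oxide and arginine genes, which stand close to the target of L-NAME, were not called for HFD + L-NAME against chow in any tested class or over all cells (median 0.15 in classical monocyte-like cells, 6 of 9 members above 0, camera adjusted p = 0.351). For NO2-OA against HFD + L-NAME they fell over all cells, with 1 of 13 members above 0 and a median of −0.33 (adjusted p = 0.00156; adjusted p = 0.498 with an estimated correlation). Gucy1b1, a subunit of the nitric oxide receptor guanylate cyclase, had −2.77 ± 0.63 and Ass1, an enzyme of arginine supply, −0.35 ± 0.28 (n = 1 and 2). The median was −0.19 and −0.77 against each HFD + L-NAME library and −0.77 without the first, and the platelet markers of the same libraries had a median of −3.60. Gucy1b1 was among the leading genes of platelet-like cluster 9, which held 58 NO2-OA cells and 74 and 1406 HFD + L-NAME cells, so its fall may follow the platelet share.

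Among neutrophil-like cells, cluster 25, led by Camp, Ngp and Ltf, granule genes of immature neutrophils, held 118 cells, of which 76 lay in the NO2-OA library, 13 and 23 in the HFD + L-NAME libraries and 6 and 0 in the chow libraries. Among B-like cells, cluster 11, led by Sox5 and Zbtb32, held 266 and 309 chow, 289 and 528 HFD + L-NAME and 258 NO2-OA cells. An unnamed cluster with the dendritic-cell genes Siglech and Cd209a, cluster 20, held 122 and 155, 87 and 102, and 12 cells. These shares were not tested.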
